A study of Homo sapiens with 6 samples.

How the data were processed

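The series held 6 1-colour Agilent arrays of OCI-AML3 cells, 3 transduced with an empty retroviral vector and 3 with the same vector carrying LIN28B, and the titles of the samples gave the group and the replicate number. Per the labels' protocols, cells were selected with puromycin and grown for several days, RNA was extracted from frozen cells, and Cy3-labelled cRNA was made from it. Per the file headers, spot intensity was extracted with Agilent Feature Extraction 10.7.1.1, which subtracted the background and corrected trends across the array to give the deposited processed signal, an intensity that was not normalized between arrays. Each deposited array file held 62976 spots, of which 1439 were controls. The array design was annotated on the hg19 build, per the file headers. The authors also deposited a table of log2 values with 57244 rows, 68 of them for control probes. Its columns had medians of 5.22 to 5.23 and near-equal quantiles, and correlated at 0.988 to 0.991 across probes with log2 of the scanner signal of the same array (probes are not independent replicates). The method that normalized them between arrays is not given in the sources used here, and the submitters' processing notes name limma with no step. This table served as an alternative.

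For the main values, log2 of the processed signal was taken and the 75th percentile of each array's non-control spots without an outlier flag was subtracted. The 75th percentile of the signal lay between 426 and 645. Control spots and spots flagged as outliers (189 to 412 per array) were left out, and spots of one probe were averaged, which gave 57176 probes. A probe was tested if it was well above background on every array of at least 1 group and had at least 2 values in each group. The fit was limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the group as the only term, two-sided, with Benjamini-Hochberg adjustment over the 28420 probes tested and a threshold of 0.05. A gene was represented by its tested probe with the highest mean over all 6 arrays and kept the adjusted p from all probes.

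Gene names came from the accessions in the array files through a RefSeq gene table of assembly GRCh38.p14, used for names only. Of 27252 probes with a RefSeq accession, 25729 (94.4%) matched 1 symbol each, for 19722 symbols, and 1523 did not match. In all, 31447 probes stayed unnamed, many of them probes for noncoding transcripts with other kinds of identifier. No coordinates are given because the table and the array use different builds.

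Before the data were examined, 26 gene lists, the alternatives and the rule for named genes were fixed. The rule took LIN28B and H19, then the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with no overlap between the groups and an absolute log2 change of at least 0.58, leaving out identifiers that are not gene symbols. The rank used the log2 difference, also where 1 group was at background. It added up to 4 members of each list with the smallest p, members a list is known for (HMGA2, IGF2BP1, IGF2BP3, MYC, IGF2, HBG1, HOXA9 and CD14), and up to 5 noncoding RNAs per direction. Lists with at least 5 members measured on every array were tested with camera at a preset correlation of 0.01, over 1 probe per gene, with adjustment over the 24 lists tested, and again with an estimated correlation. Of these, 9 passed with the preset correlation and 0 with the estimated one. The self-contained test fry gave 0 lists for a shift in one direction and 8 for changes in either direction. Of those 8, let-7 targets, cancer lncRNAs, monocyte and granulocyte markers and the MYC list had also passed camera with the preset correlation. Imprinted genes, antigen presentation genes, lymphocyte markers and fibroblast and epithelial markers had not. Members were also adjusted over the list alone. Some members' own values are not reported here.

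Limma was tested on simulated data with the real probes' means and spread in the LIN28B against empty vector comparison, over 28146 probes. Of 50 probes changed by a log2 value of 1, 32% were recovered, and 64% at 2, 90% at 3 and 92% at 4, with 4 false calls among 143. The simulated noise was drawn independently for each probe and array, without correlation between probes or an effect of slide row or signal strength. The false calls are therefore not a rate for the real calls.

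The 2 principal components that explained most held 36.5% and 23.6% of the variance, the first separating the groups. Pearson's r between arrays lay between 0.977 and 0.989 across probes, with a lowest value of 0.983 within groups and a highest of 0.987 between them. The alternatives were another background correction, quantile normalization and median centring, the authors' deposited values, other filters on dim probes, a floor, an intensity trend with robust variance, array weights, the replicate number or the slide row as a block, the slide row with both groups alone, each array left out in turn, the mean of all probes of a gene, and camera with an estimated correlation. The mean spot signal was not among the columns of the files, so the background alternative used normexp with an offset of 50 on the median spot signal. The offset is larger than the median processed signal of each array (24 to 32), so it shrinks the log2 changes of dim probes by construction. A planned test of let-7 seed matches in 3' untranslated regions was left out because it needs transcript sequences, which were not used here.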

Results

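RNA levels were measured in OCI-AML3, a human cell line from acute myeloid leukaemia that carries an NPM1 mutation. The cells had been transduced with a murine stem cell virus (MSCV) retroviral vector that carries puromycin resistance and GFP, either with LIN28B inserted or empty, and were selected with puromycin. LIN28B is an RNA-binding protein that blocks the maturation of the let-7 microRNA family. Each group held 3 samples, each hybridised to its own 1-colour microarray with probes for messenger RNAs and long noncoding RNAs. All 6 arrays lay on 1 slide and were read in 1 scan. Between 31814 and 36074 of 61537 non-control spots per array were well above background, and 0 spots were saturated. Levels are given as log2 of the processed signal minus the 75th percentile of that array, so a level of 0 is the 75th percentile. Probes differ in their response, so a level is compared only with the same probe on another array. The labels do not say whether the samples of a group came from separate transductions or cultures, so p-values measure only the spread between these samples. With 3 arrays per group, the number of arrays limits the precision of every value.

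The array had 1 probe assigned to LIN28B (NM_001004317), and it was not well above background on any of the 6 arrays. Its level was −7.30 ± 0.31 (SD, n = 3) in the empty vector group and −7.54 ± 0.46 (SD, n = 3) in the LIN28B group. The position of this probe in the transcript is not known here. A probe outside the inserted part of the transcript does not read the vector's RNA, whereas for a probe inside it these levels would go against the label. The files used here do not tell which holds, so the overexpression was left unchecked. LIN28A, the paralogue of LIN28B, was below background on all 6 arrays too.

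The series names H19, an imprinted long noncoding RNA, as a target of LIN28B, and its probe (NR_002196) was above background on 3 of 3 LIN28B arrays and 1 of 3 empty vector arrays. The levels in LIN28B replicates 1 to 3 were −3.00, −2.60 and −3.62. In the empty vector group, replicate 2 lay at −2.90, inside the LIN28B range, and replicates 1 and 3 at −6.29 and −6.99. The mean log2 change was 2.32 (SE 0.99), which did not pass the test (limma, adjusted p = 0.443). Its size is poorly fixed, because replicates 1 and 3 of the empty vector group were at background. With another background correction (normexp), whose offset shrinks the changes of dim probes, the change was 0.45. IGF2, the imprinted neighbour of H19, was above background on 1 LIN28B array with each of its 2 probes and on no empty vector array.

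LIN28B-transduced cells had higher RNA levels of 45 genes and lower levels of 24 among 13955 genes tested. ALDH1A3 (NM_000693), a retinaldehyde dehydrogenase, rose from −3.33 ± 1.09 to 1.25 ± 0.28 (SD, n = 3 each), a log2 change of 4.58 (SE 0.50, limma adjusted p = 0.0251; 3.41 with the normexp background correction). GZMA, the protease granzyme A, rose by 4.35 on the log2 scale (SE 0.48, limma adjusted p = 0.0251; 3.91 with normexp). FAP, a serine protease of activated fibroblasts, rose by 4.02 (SE 0.32, above background on 2 of 3 empty vector arrays, 2.45 with normexp), and CD163, a haemoglobin scavenger receptor of macrophages, by 3.87 (SE 0.42; 3.48 with normexp). ANKRD22 and CEP15 rose by 3.68 (SE 0.39) and 3.08 (SE 0.27), each from a level above background on only 1 of 3 empty vector arrays, and by 1.45 and 1.25 with another background correction (normexp).

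The other 6 of the 12 genes with the largest log2 difference upward were not well above background on any empty vector array, so their change has only a lower bound and their rank is not a rank of measured rises. SFRP2 and JAML, which ranked below them and were chosen after their values were seen, rose by more than any of these bounds (7.35-fold and 7.34-fold, above background on all 6 arrays). That bound sets the mean of the LIN28B arrays against, on each empty vector array, the higher of the probe's own signal and the lowest signal well above background. It carries no error term, so each "at least" value is a limit on the difference of means in these samples. Single arrays can fall short of it. SALL4, a zinc finger transcription factor of embryonic stem cells, was at least 4.26-fold higher in LIN28B cells, GALNT14, a glycosyltransferase, at least 5.32-fold, and EPB41L4A at least 5.23-fold. CIITA, the transcriptional activator of MHC class II genes, was at least 2.53-fold higher (limma, adjusted p = 0.0216) and the class II chain HLA-DRA at least 2.09-fold higher (limma, adjusted p = 0.00774). PIGR, the polymeric immunoglobulin receptor, was at least 2.51-fold higher. These bounds hold for the main background correction only. With normexp and an offset, none of the 6 was called, and the log2 change was 0.68 for SALL4, 0.60 for CIITA, 0.65 for PIGR, 0.36 for HLA-DRA and 1.01 for EPB41L4A, each below its bound. In the authors' deposited value table GALNT14 had a log2 change of 0.26 and was not called. A further CIITA probe, above background on 1 LIN28B array and no empty vector array, was not tested, and its mean was lower in LIN28B cells (−5.24 against −5.00).

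Among the falls, AOPEP, an aminopeptidase, dropped by 2.72 on the log2 scale (SE 0.29, limma adjusted p = 0.0245), from 0.85 ± 0.47 to −1.87 ± 0.36 (SD, n = 3 each), but a second AOPEP probe, above background on all 6 arrays, had a log2 change of only −0.25 (limma, adjusted p = 0.739). TSPAN5, a tetraspanin, fell by 2.34 (SE 0.27), and KCNQ1, an imprinted potassium channel gene, fell by 2.01 (SE 0.25, limma adjusted p = 0.0337). MEGF6 and KHDRBS2 were not well above background on any LIN28B array and were at least 3.30-fold and at least 2.14-fold lower there. SGMS2, a sphingomyelin synthase, fell by 1.99, MMRN2 fell by 1.72, CRISPLD1 fell by 1.70 (above background on 1 of 3 LIN28B arrays) and the kinase NUAK1 fell by 1.65. AHNAK, a very large scaffold protein, fell by 1.63 (SE 0.14) at the probe that stands for it. FSTL4 and ZNF462 had log2 changes of −1.54 and −1.53. The only named noncoding RNA that fell was the pseudogene MBL1P, with a log2 change of −1.33. With normexp, whose offset shrinks the changes of dim probes, MEGF6 (−0.71), KHDRBS2 (−0.45), CRISPLD1 (−0.56), FSTL4 (−0.79) and MBL1P (−0.57) were not called. SGMS2 (−1.11) and MMRN2 (−0.89) were called with smaller changes. A noncoding RNA outside the naming rule, LOC100240735, chosen after its values were seen, was at least 4.12-fold higher in LIN28B cells.

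**Figure D1:**
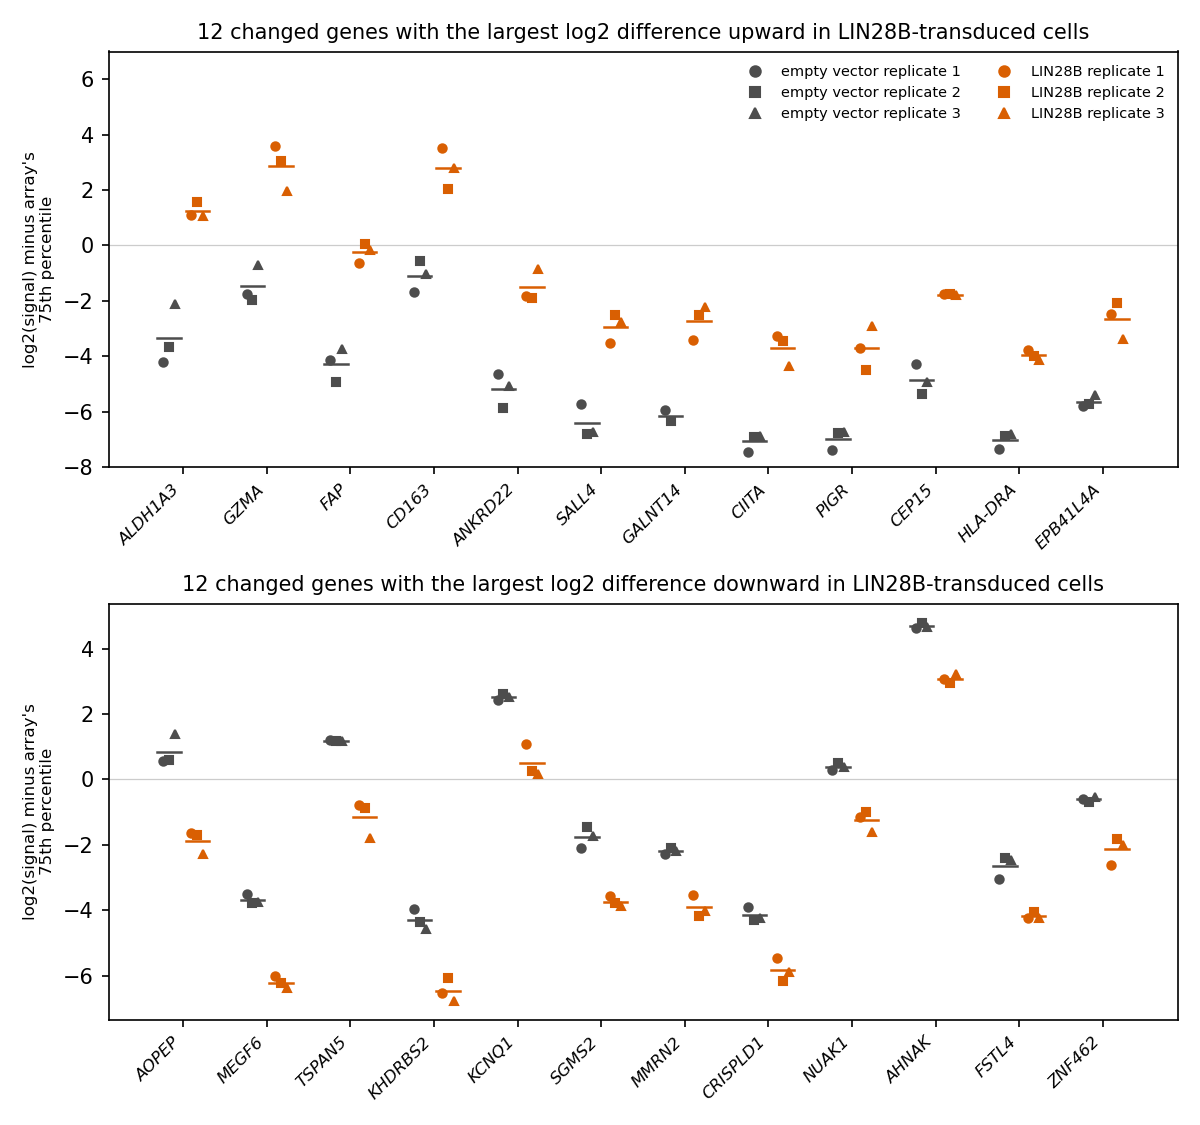
Levels on each array (points) and group means (lines) of the 12 changed genes with the largest log2 difference upward and the 12 with the largest downward, as log2 signal minus the array's 75th percentile; grey marks the empty vector group and orange the LIN28B group. The arrays of one group lie above those of the other for each gene (GALNT14 has no value in empty vector replicate 3), and ALDH1A3 goes from a mean of −3.33 to 1.25.

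At the level of probes, 119 of 28420 tested changed at an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment, two-sided), 73 higher and 46 lower, and 117 of them by at least 2-fold. At an unadjusted p of 0.05, 3212 probes (11.3%) passed. The arrays of one group lay above those of the other for 4990 probes (17.6%) and for all 119 changed probes. Chance would give 10% for a filter blind to the groups and probes without missing values. The filter on dim probes used the groups, which favours such a separation, and 274 tested probes lacked a value. The 17.6% therefore cannot be weighed against 10%. The 119 were called for their difference between the groups, so their separation adds little. Another scaling moved the share of rises: 61.3% of the changed probes were higher here, 78.8% under median centring (165 probes changed) and 73.6% in the authors' deposited value table (125 probes changed).

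The counts rested on every array: without empty vector replicate 1, 2 or 3, 75, 8 and 11 probes changed, and without LIN28B replicate 1, 2 or 3, 24, 3 and 19. The corresponding numbers of genes were 39, 5, 8, 15, 2 and 12, and each of the 26 changed genes named by rule lost its call in at least 1 of these 6 fits. All 3 LIN28B arrays and empty vector replicate 1 lay in 1 row of the slide, and empty vector replicates 2 and 3 alone in the other. With slide row as a block, 0 probes passed the adjusted threshold (limma, 2079 at an unadjusted p of 0.05). The median absolute log2 change of the 119 changed probes was 1.73 there, against 1.80 without the block, though they were picked from the same arrays. The block contrast sets the 3 LIN28B arrays against empty vector replicate 1 alone. A fit within the row that held both groups has the same contrast, so it is not a separate check.

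Let-7 target genes lay higher in LIN28B cells as a group: 21 of the 28 tested members had log2 changes above 0, with a median of 0.27. The shift passed the set test against other genes (camera with a preset correlation, adjusted p = 0.00596) but not with the correlation between genes estimated from the arrays (adjusted p = 0.66 with an estimated correlation). The only member that rose over all genes tested was IGF2BP1, an RNA-binding protein of embryonic and cancer cells, with a log2 change of 1.68 (SE 0.18, limma adjusted p = 0.0245). Adjusted over the list alone, 3 members passed: IGF2BP1, the chemokine receptor CCR7 and the transcription factor ARID3A (log2 change 0.63, limma adjusted p = 0.183). CCR7 was at background on the empty vector arrays and at least 1.64-fold higher by the group means (limma, adjusted p = 0.154 over all genes tested). Its log2 change under normexp was 0.31. In LIN28B replicate 1, CCR7 (−5.49) lay below the lowest signal well above background on every empty vector array (−5.40 to −4.83). Other known targets did not pass: the log2 change was 0.46 for DICER1, 0.26 for MYC, 0.04 for HMGA2 and −0.00 for IGF2BP3. CCND1 (−0.73) and CDK6 (−0.57), chosen after their values were seen, lay on the other side, and at an unadjusted p of 0.05, 7 members were higher and 1 lower. With slide row as a block, a contrast that rests on a single empty vector array, the shift of the list missed the threshold (camera, preset adjusted p = 0.0661). None of the 9 tested let-7 targets of the insulin and mTOR pathways passed (median log2 change −0.01), nor did the 2 tested host transcripts of let-7 precursors, HUWE1 and MIRLET7BHG.

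Of 17 imprinted genes tested, KCNQ1 fell. Adjusted over the list alone, KCNQ1OT1, the antisense noncoding RNA from the KCNQ1 locus (log2 change −0.70, limma adjusted p = 0.187 over all genes tested), and IGF2R (0.64, 0.232) passed as well. The list as a whole did not shift (camera, adjusted p = 0.78, direction down, with a median of 0.10 and a mean of 0.05). Long noncoding RNAs studied in leukaemia and other cancers had log2 changes below 0 for 14 of 19 members, with a median of −0.18 (camera, preset adjusted p = 0.0109; adjusted p = 0.66 with an estimated correlation). None passed the test singly, over all genes tested or over the list alone, and 2 were lower at an unadjusted p of 0.05. CYTOR and ZFAS1 had log2 changes of −0.55 and −0.42, nearer 0 under median centring and with slide row as a block. With slide row as a block the shift of this list had a preset adjusted p of 0.241. Its median was 0.01 under median centring, which put the median of all genes tested at 0.21, against 0.02 under the main scaling.

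Monocyte and granulocyte markers had a median log2 change of 0.50 (0.30 with normexp), with 18 of 26 members above 0. The set test gave a preset adjusted p of 0.0109 (camera), and an adjusted p of 0.69 with an estimated correlation. With each member centred on its own mean over the 6 arrays, the members averaged 0.87 in LIN28B replicate 3, against 0.15 and 0.14 in replicates 1 and 2. The empty vector replicates averaged −0.65, −0.18 and −0.33. Without LIN28B replicate 3 the list missed the threshold (camera, preset adjusted p = 0.113). CD163 rose, as given above. FCN1 (log2 change 2.94) and VCAN (2.16) passed only when adjusted over the list alone, with limma adjusted p = 0.183 and 0.217 over all genes tested. CD14, the endotoxin co-receptor of monocytes, differed within the LIN28B group, at 1.91 in replicate 1, 7.41 in replicate 2 and 6.18 in replicate 3, against 1.61, 3.07 and 2.29 in the empty vector replicates (log2 change 2.84, SE 1.30, limma adjusted p = 0.476). NF-kB genes had a median of 0.31, with 12 of 17 members above 0 (camera, preset adjusted p = 0.0109; adjusted p = 0.69 with an estimated correlation). None of them passed over all genes tested, and 4 passed adjusted over the list alone: IER3 (log2 change 1.90, and 1.22 without LIN28B replicate 3), ICAM1 (1.02), CXCL1 (0.92) and CCL20 (at least 1.59-fold, at background on the empty vector arrays, with a log2 change of 0.12 under normexp). Without LIN28B replicate 3 this list missed the threshold too (preset adjusted p = 0.0536).

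**Figure D2:**
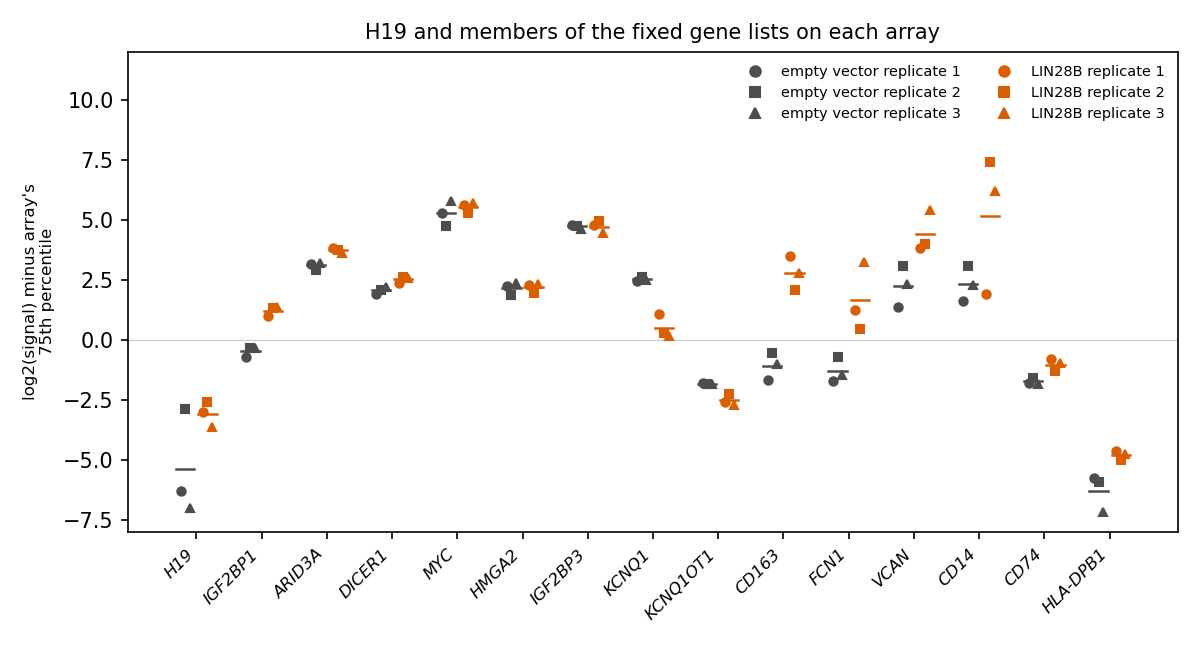
Levels on each array (points) and group means (lines) of H19 and of members of the gene lists, as log2 signal minus the array's 75th percentile; grey marks the empty vector group and orange the LIN28B group. H19 in empty vector replicate 2 (−2.90) lies among the LIN28B arrays, and CD14 in LIN28B replicate 1 (1.91) lies among the empty vector arrays.

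Of 20 tested antigen presentation genes, CIITA and HLA-DRA rose and none fell. Adjusted over the list alone, HLA-DPB1 and CD74 (log2 change 0.70) passed as well, with limma adjusted p = 0.215 and 0.216 over all genes tested. HLA-DPB1 was at background on the empty vector arrays and at least 1.17-fold higher by the group means, with a log2 change of 0.12 under normexp. In LIN28B replicate 2, HLA-DPB1 (−5.01) lay below the lowest signal well above background on empty vector replicates 2 and 3 (−4.85 and −4.83). The median of the list was −0.02 and its mean 0.48, and the list did not pass the set test (camera, adjusted p = 0.146). It passed upward in 2 of 20 alternatives, 1 of them without LIN28B replicate 1 (camera, preset adjusted p = 0.0451). HLA-DPA1 had 2 tested probes, of which the dimmer rose by 1.66 (limma, adjusted p = 0.0264) and the brighter, which stands for the gene, had a log2 change of −0.05. Interferon-induced genes had log2 changes below 0 for 23 of 27 members, with a median of −0.22 (camera, preset adjusted p = 0.0109; adjusted p = 0.87 with an estimated correlation). None of them passed singly, and 2 were lower at an unadjusted p of 0.05. Without LIN28B replicate 3 the list missed the threshold (preset adjusted p = 0.0774), and under median centring its median was −0.02, with that of all genes tested at 0.21. RSAD2 had a log2 change of −0.73.

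Genes of the MYC and nucleolar list had small changes, with 22 of 24 members above 0 and a median of 0.22 (camera, preset adjusted p = 0.000775; adjusted p = 0.66 with an estimated correlation). No member passed singly, and 4 were higher at an unadjusted p of 0.05. Glycolysis genes had a median of 0.20, with 15 of 20 above 0 (camera, preset adjusted p = 0.0109; adjusted p = 0.84 with an estimated correlation). No member passed over all genes tested, and PFKFB4 (log2 change 1.13) and PFKM (1.22) passed adjusted over the list alone. Without LIN28B replicate 3 the glycolysis and cholesterol lists missed the threshold (preset adjusted p = 0.106 and 0.277). Cholesterol synthesis genes had a median of 0.14, with 20 of 22 above 0 (camera, preset adjusted p = 0.02; adjusted p = 0.69 with an estimated correlation), and no member passed (2 higher at an unadjusted p of 0.05). Red cell genes had a median of −0.15, with 11 of 13 below 0 (camera, preset adjusted p = 0.02; adjusted p = 0.69 with an estimated correlation), and no member passed (2 lower at an unadjusted p of 0.05), HBG1 having a log2 change of −0.02. Under median centring their median was 0.04, but that scaling also moved the median of all genes tested from 0.02 to 0.21. With slide row as a block the set test missed the threshold (camera, preset adjusted p = 0.118).

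Markers of other cell types were measured beside these groups. Among fibroblast and epithelial markers, of which 6 of 18 were tested, FAP rose, and adjusted over the list alone COL1A2 passed in the other direction (log2 change −1.19, limma adjusted p = 0.3 over all genes tested, −0.50 under normexp). FN1 had a log2 change of 1.90 (above background on 1 of 3 empty vector arrays, 0.33 under normexp), and the set test did not pass (camera, adjusted p = 0.78, direction up, with a median of −0.10 and a mean of 0.71). Of 11 tested T and B lymphocyte markers none passed over all genes tested, and the adaptor BLNK (at least 3.22-fold, at background on the empty vector arrays, with a log2 change of 0.60 under normexp, limma adjusted p = 0.115) passed adjusted over the list alone. That list had a median of −0.14 and a mean of 0.32 (camera, adjusted p = 0.78, direction down). The 5 tested megakaryocyte markers, too few with complete values for the set test, had a median of −0.18, and GP9 (−0.64) and GP1BB (−0.72) passed adjusted over the list alone.

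The other 10 lists did not pass the set test, and no member of them passed over all genes tested or over the list alone. The median log2 change was 0.08 for HOX and stem cell genes of AML (19 tested, HOXA9 at 0.13), 0.18 for DNA replication (28 tested) and 0.00 for mitosis (26 tested). It was 0.13 for p53 targets (22 tested, 1 higher at an unadjusted p of 0.05), 0.11 for oxidative phosphorylation (28 tested) and −0.06 for cytosolic ribosomal proteins (37 tested). Stress genes of the ATF4 and unfolded protein responses (23 tested) had a median of 0.07, hypoxia genes 0.04 (14 tested, 1 higher unadjusted) and replication-dependent histones −0.09 (23 tested). Immediate early genes had a median of 0.05, with 4 of 19 higher and 2 lower at an unadjusted p of 0.05. With slide row as a block, 3 of these lists passed: histones downward, oxidative phosphorylation upward and the ATF4 list downward (camera, preset adjusted p = 1.10e-05, 0.0132 and 0.0224). With an estimated correlation and no block, camera gave adjusted p = 0.93, 0.93 and 0.98. The block contrast rests on empty vector replicate 1, the only empty vector array in the row of the LIN28B arrays. With each histone gene centred on its own mean over the arrays, the list averaged 0.52 in that replicate. It averaged −0.02 and −0.34 in empty vector replicates 2 and 3, and 0.44, −0.24 and −0.37 in LIN28B replicates 1 to 3. Over all 20 alternatives, oxidative phosphorylation passed in 8 and histones in 5. The fit within the row that held both groups has the same contrast as the row block, so it is not a separate check. DNA replication passed upward without LIN28B replicate 3 (preset adjusted p = 1.17e-07; on all arrays adjusted p = 0.93 with an estimated correlation). The median of the ribosomal proteins was above 0 under quantile normalization (0.04), under median centring (0.13) and in the authors' deposited value table (0.04). Median centring put the median of all genes tested at 0.21, against 0.02 under the main scaling.

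**Figure D3:**
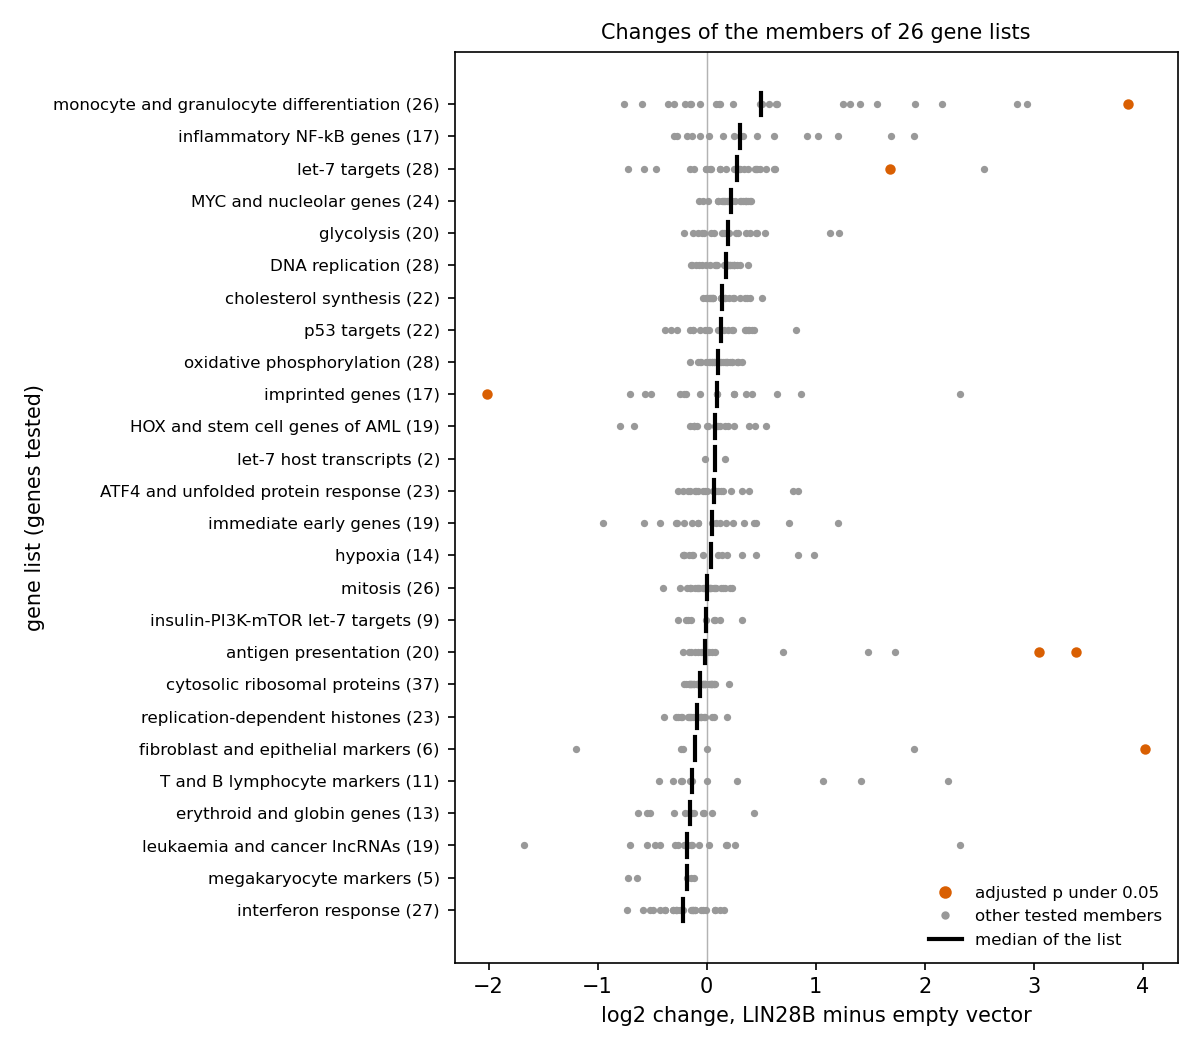
Log2 change, LIN28B minus empty vector, of each tested member (points) of the 26 gene lists, with the median of each list (black bars) and the number of genes tested in parentheses; orange points passed an adjusted p of 0.05 over all probes tested. The medians lie between −0.22 (interferon response) and 0.50 (monocyte and granulocyte differentiation), and 6 points in 5 lists passed.

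Probes without a gene name made up 42 of the 119 changed probes, 23 higher and 19 lower. Those well above background on all 6 arrays rose by up to 3.74 on the log2 scale. Probe CUST_5212_PI427704219 (transcript ENST00000412788), at background on the empty vector arrays, was at least 6.08-fold higher in LIN28B cells (limma, adjusted p = 0.00934). Probe CUST_5_PI427704219 (ENST00000436715) was at least 3.17-fold higher (limma, adjusted p = 0.00774). Among the falls, probe CUST_14646_PI427704219 was at least 4.67-fold lower and probe A_33_P3214129 (AK025151) had a log2 change of −2.77 (SE 0.26). Bounds on these probes and on LOC100240735 hold for the main background correction only. These transcripts, and any further probe of H19 among the 31447 unnamed ones, could not be matched to a gene with the table used here.

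Probes of one gene did not always give the same call. All of the tested probes were called for EMP2 (2 of 2), 2 of 3 for AHNAK, and 1 of 2 for AOPEP, NPR3, PREX2, ISYNA1 and TSPAN32, with changes of one sign. For SYT2 1 of 5 probes was called, and for PTGER3 and PTPRC 1 of 4.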

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

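All alternatives in this part were set before the data were examined. One was altered once the files were open: the background alternative used the median spot signal because the mean is not among the columns of the files used here. Of 119 changed probes in the main setting, all 119 kept their sign in every setting that tested them, except the authors' deposited value table, where 118 did; they were picked from the same arrays, and the calls themselves moved more. No probe or gene was called without a filter on dim probes (0 of 57163 probes by limma, 3391 at an unadjusted p of 0.05). The main setting tested 28420. With slide row as a block, 0 probes and 0 genes were called (limma, 2079 probes unadjusted). That fit and the one within the slide row that held both groups share 1 contrast, the LIN28B arrays against empty vector replicate 1 alone. A fit with the replicate block called 0 probes and 0 genes (4302 probes unadjusted). Whether arrays of the same replicate number form pairs stays open, so the main fit may leave out a pairing. The deviations of same-numbered arrays correlated at 0.328, 0.0968 and 0.119 across probes. Each array correlated best with its own number, a hint from the data only. More probes passed unadjusted with the replicate block than in the main fit (limma, 4302 against 3212), despite fewer residual degrees of freedom. Array weights gave 292 probes and 161 genes, and an intensity trend with robust variance 114 genes (176 probes), against 69 genes in the main setting. The cause was not tested. The mean of all probes of a gene gave 107 genes. Its p-values were adjusted over genes, whereas the 69 were adjusted over the 28420 probes, so these 2 counts are not directly comparable. Leaving out 1 array gave 3 to 75 probes, 2 to 39 genes and 3 to 11 gene lists, with fewer samples in each fit. The 9 lists became 3 without empty vector replicate 1, 6 without LIN28B replicate 3 (5 lost, 2 gained), 9 with slide row as a block (3 lost, 3 gained) and 0 with an estimated correlation. Mitosis genes, with no shift in the main setting, shifted up without LIN28B replicate 3 (camera, signed −log10 p of 1.93, preset adjusted p = 0.0465; adjusted p = 0.98 with an estimated correlation on all arrays) and down without LIN28B replicate 1 (−1.97, preset adjusted p = 0.026), so this list depends on single arrays. H19 kept its direction and missed the threshold in each setting that tested it, with log2 changes from 0.45 (normexp background correction) to 3.57 (without empty vector replicate 2, both other arrays of that group at background); the LIN28B probe stayed at background, with differences of −0.50 to −0.05 without 1 array. Of the 26 changed genes named by rule, 14 were called under all 4 other scalings, and 0 in all 6 fits without 1 array. Over all alternatives the named genes gave 255 calls lost and 0 gained, and the lists 42 lost and 23 gained. In 20 alternatives each, red cell genes lost their shift in 9, lncRNAs and monocyte markers in 6, and interferon and cholesterol genes in 5. NF-kB genes lost theirs in 4, let-7 targets and glycolysis in 3 and the MYC list in 1. Oxidative phosphorylation gained a shift in 8, histones in 5, DNA replication in 3 and antigen presentation in 2. Median centring moved the median log2 change of tested probes from −0.04 to 0.15. Signal over background limits 24 of the changed probes, dim in all arrays of 1 group, to a bound. The planned let-7 seed match test was not run.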

Other observations

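The genes named in this paragraph were chosen after their values were seen, and the comparison is the same limma fit. SFRP2, a secreted modulator of Wnt signalling, rose by 2.88 on the log2 scale (SE 0.34, limma adjusted p = 0.0297) and the adhesion molecule JAML by 2.88 (SE 0.40). SLAMF7 (log2 change 2.45, above background on 1 of 3 empty vector arrays), GPR34 (2.61, on 2 of 3) and CD180 (1.58) rose too. SPIB, an ETS family transcription factor of B cells and plasmacytoid dendritic cells, rose by 1.98, and IFI30, a lysosomal thiol reductase of class II antigen processing, by 1.24. Among the falls, DEPTOR, an inhibitor of mTOR, had a log2 change of −1.21, LTC4S, the leukotriene C4 synthase, of −1.33, CST7, a protease inhibitor of blood cells, of −1.23, and the cadherin FAT1 of −1.52. The homeobox genes DLX4 (−1.25) and ONECUT2 (−1.44) fell too.

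The tests on splits, slide row, signal strength, interferon and B lymphocytes in the paragraphs that follow were chosen only after the results were seen.

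The first pattern is the 119 probes and 69 genes called between the groups. Setting the 3 arrays with most spots above background against the rest called 0 probes (limma, 1794 at an unadjusted p of 0.05). Every split that mixed the groups called 0, since mixing puts a group difference into the residual spread. The count therefore cannot weigh signal strength as a cause of the calls. An effect of the slide row cannot be told apart from the groups, because only 1 empty vector array lay in the row of the LIN28B arrays. Splitting the arrays by row, 2 against 4, called 6 probes, the most of the 15 such splits (highest other 1), and passed 2526 at an unadjusted p of 0.05, against 3212 for the groups in their 3 against 3 split. With slide row as a block the median absolute log2 change of the 119 probes was 1.73, against 1.80 without it. Its median SE was 0.28 against 0.20, and the block fit has fewer residual degrees of freedom. No call was left, while all 119 passed an unadjusted p of 0.05 (limma), as did 2079 probes in all. These 119 were picked from the same arrays, so this comparison says little about the row. The 10 splits of the 6 arrays are too few for a share under 0.05. The real split called 119 probes and 69 genes, each the highest of the splits (1 of 10), and the highest other called 0 of both. The filter on dim probes used the real groups, which favours the real split. At an unadjusted p of 0.05, empty vector replicates 1 and 2 with LIN28B replicate 1 against the rest passed 2774 probes (limma), against 3212 for the groups. An effect of LIN28B, of the slide row or of signal strength stays open. So do a difference between transduced cell pools and a shared handling of each group.

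The second pattern is the 9 gene lists past the camera threshold with a preset correlation. Setting the 3 arrays with most spots above background (empty vector replicate 1 and LIN28B replicates 1 and 2) against the rest put 12 lists past it, which points to a structure of the arrays beyond the groups. In line with this, the second principal component followed the number of spots above background (Pearson r = 0.916, exact permutation p = 0.0181; Spearman rho = 0.886, exact permutation p = 0.0333; both 0.0333 after Benjamini-Hochberg adjustment over the 2; n = 6), with r = 0.949 over the 4 arrays left without the 2 farthest from the median. The second component and the number of spots above background both fell from replicate 1 to 3 in each group, so signal strength and replicate order cannot be told apart. Among the 10 splits, too few for a share under 0.05, 4 put 9 or more lists past the threshold, with 12 in the highest other. The median log2 change of let-7 targets was larger in the real split than in any other (0.27, against an absolute value of at most 0.22). So were those of MYC and nucleolar genes (0.22 against 0.12) and of monocyte and granulocyte markers (0.50 against 0.29). Those of the other 6 lists were not, nor was that of any other list compared. By chance a list is largest in the real split in 1 of 10 cases, and the 9 lists were picked because they passed there. This comparison therefore does not single out these lists.

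The third pattern is the rise of CIITA and HLA-DRA from background. The interferon list had a mean log2 change of −0.22 in LIN28B cells (95% interval −0.84 to 0.41 from the 6 array means). That lies below the 1.06 that the smaller lower bound of the pair sets on the log2 scale. These values argue only against an interferon exposure that raises the listed genes, on average, by as much as this bound. An exposure that raises CIITA and HLA-DRA more than the listed genes was not tested, so interferon in the LIN28B cultures stays open. Even the narrower argument holds for the main background correction only: with normexp the log2 change of HLA-DRA was 0.36, inside that interval. A few B lymphocytes in the LIN28B cultures cannot be told apart from a change in the leukaemia cells: of CD79A, CD79B, MS4A1 and PAX5, 0 were above background on more LIN28B than empty vector arrays, but 3 of them were at background on all arrays. CD79A, above background on all 6 arrays, had a log2 change of −0.15, and CD74, abundant in B lymphocytes, of 0.70. Regulation of CIITA downstream of LIN28B is an untested hypothesis.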
